A study of Homo sapiens with 69 samples.

How the data were processed

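RNA was measured in 69 libraries of BEAS-2B cells, an immortalized human bronchial epithelial line, by stranded poly(A) RNA sequencing. Cells were exposed to 1 of 3 graphene oxide (GO) materials, which the labels call GO-US, GO-S and GO-L, or left untreated. The labels place the short-term samples at 1 day, while the series protocol describes an exposure of 48 h, so they are called short-term here. Long-term samples received 1 or 5 µg/mL repeatedly and were harvested after 7 d or 28 d. At 4 weeks these doses add up to 8 and 40 µg/mL.

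The authors deposited a table of raw counts, with a whole number of reads per gene and library, for 63677 Ensembl genes on build GRCh37. They also deposited TPM values in a separate file per sample. Per the labels, the software was bcl2fastq 2.19.1.403, CASAVA, STAR 2.5.1b, featureCounts 1.5.1 and StringTie 1.3.3; which step each tool served, the annotation release and the strand setting were not given. TPM summed to 1000000 in every deposited file. Each of the 69 columns of the count table, centred on the log scale, correlated best with the TPM of the sample it was mapped to. In the count table, 25167 genes were at 0 in every library. Repeated gene identifiers in the TPM files, 646 entries over all files, were summed.

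Depth, in M (1 M is 1000000 reads), ranged from 36.9 to 72.4 M counted reads per library with a median of 56.6 M. Between libraries of a group, chi-square over degrees of freedom had a median of 18.5 over genes with at least 20 reads in the pair, where counting error alone gives 1. This value pools genes of all levels, those near 1 CPM (counts per 1000000 of the library total) among them. Short-term libraries held 44.3 to 69.7 M reads, 7 d libraries 36.9 to 67.0 M and 28 d libraries 44.9 to 72.4 M. Mitochondrially encoded genes took 3.40 to 8.05% of the reads and the 10 most abundant genes 4.33 to 8.94%.

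Counts were analysed with edgeR 4.0.16 in R 4.3.3. Each time set was fitted alone with 1 mean per group, after filterByExpr (minimum count 10, minimum total count 15) and TMM size factors. Tests were edgeR's quasi-likelihood F-tests with robust estimates of the spread, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Genes tested numbered 18896 in the short-term set, 16449 at 7 d, 17579 at 28 d and 20359 when the short-term and 28 d sets were fitted together. Log2 changes are given with their standard errors (SE), levels as CPM with the standard deviation (SD) between libraries. All adjusted p-values for genes in the text come from edgeR unless another tool is named. P-values measure the spread between these libraries; the labels do not say whether replicates were separate cultures, exposures or days.

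In total 40 results were tested. They compare the mean of the 3 materials with the control of the same time, each material with that control, the materials with each other at 1 dose (an F-test with 2 degrees of freedom), the high with the low dose, and the short-term effect with the 28 d effect at equal cumulative dose. The last is a test of the difference between effects, each taken against its own control.

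Gene lists, 35 in all, were tested by camera in limma 3.58.1 with the correlation between genes preset to 0.01 and again with the correlation estimated from the data. List p-values were adjusted over 315 list tests. Beside the members called over all genes, the count adjusted over the list alone is given. Among the lists are markers of cell types the culture could also hold: ciliated, secretory and goblet, fibroblast, haematopoietic and endothelial cells. Some lists share members: extracellular matrix shares 5 with fibroblast markers and 2 with TGF-beta and YAP targets. Metallothioneins share 2 with the retinoid and glucocorticoid list, and mesenchymal genes 2 with fibroblast markers.

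The design, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined. Named genes are those with the largest changes at a mean level of at least 1 CPM. Up to 10 per direction were taken for each mean of materials, with the same sign in the 3 materials, and up to 5 per direction for dose and time comparisons. In addition, up to 4 members per list and the 5 genes per comparison of the materials with the smallest p could be named. A subset of these is printed. Some genes that meet this rule are not reported here.

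Alternatives fixed beforehand were RLE size factors, no filter on low counts, a block for the replicate number, each replicate number left out in turn, DESeq2 1.42.0, and StringTie TPM with limma (pseudocount 1, minimum mean TPM 1). GO-S and GO-L alone were also fitted at 28 d and 5 µg/mL. Alternatives chosen after seeing the data were the removal of each library's trend on GC content, or on GC content and gene length, by lowess with a span of 0.2, leaving out each 7 d control library, both of these together, and a 28 d dose comparison without GO-US. Random lists matched to a list on GC content, length and expression were also chosen then. GC content was known for 96.2 to 97.2% of the genes tested.

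The pipeline was tested on simulated data with changes added to 200 genes per effect. For a mean of 3 materials it found 82.1, 97 and 100% of log2 changes of 0.5, 1 and 2 in the short-term set. At 28 d it found 83.6, 94 and 98.5%. Short-term, 4% of its calls were unchanged genes. With a GC trend along the order of the libraries added, this was 93.6%, and 4.3% once the trend was removed. Real libraries of a group also differed mainly along GC content (absolute Spearman 0.82, 0.9 and 0.86 short-term, at 7 d and 28 d). The 4% may not hold for them. Other splits of the samples were drawn 40 times for means, doses and material comparisons, 25 times for differences between effects, and 10 times for 3 against 3 libraries. Figures were drawn in Python 3.11.15. The single GO-US library at 28 d and 5 µg/mL gives no spread of its own and is assumed to vary like the other groups.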

Results

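The 69 libraries of BEAS-2B cells fall into 24 groups, to compare short with long exposure to graphene oxide at equal total doses. The short-term set held a control and each of the 3 materials at 8, 40 and 80 µg/mL. The 7 d and 28 d sets each held a control and the 3 materials at 1 and 5 µg/mL. Every group had 3 libraries, except at 28 d and 5 µg/mL, where GO-US had 1 and GO-L had 2. Total counts had medians of 56.5 M in the short-term set, 53.6 M at 7 d and 58.3 M at 28 d. The 3 controls at 7 d held 36.9, 39.8 and 38.8 M.

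**Figure D1:**
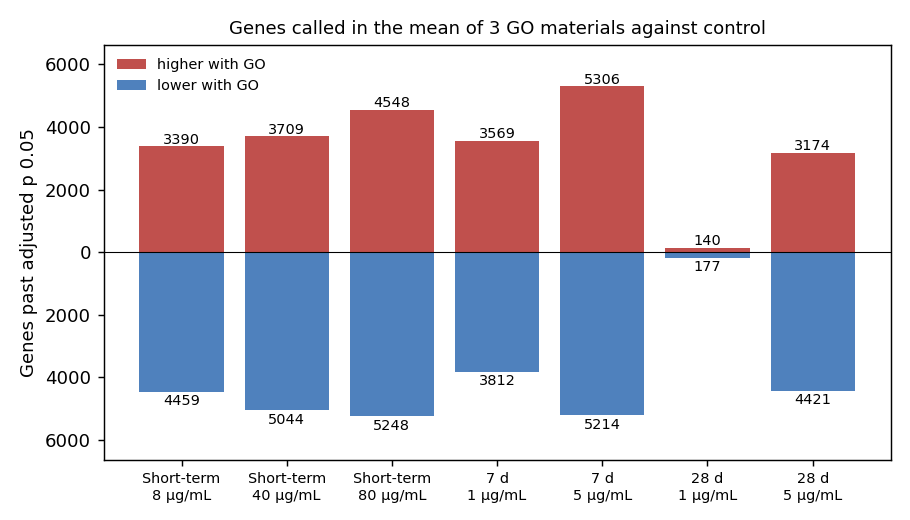
Genes past the threshold (vertical axis, number of genes, edgeR adjusted p under 0.05) in the mean of the 3 materials against control at each time and dose (horizontal axis), with higher genes above and lower genes below 0. The mean of the materials gave 317 genes at 28 d and 1 µg/mL and 10520 at 7 d and 5 µg/mL.

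Cells exposed short-term to 8 µg/mL had more RNA of the extracellular matrix and less of ribosomal proteins and of the respiratory chain. COL1A1, a chain of type I collagen (ENSG00000108821, GRCh37 chromosome 17, 48260650 to 48278993), rose by 1.83 ± 0.25 (SE, log2 scale; adjusted p = 6.4e-06) from 84.7 ± 20.4 CPM (SD, n = 3) in control cells, and ELN, the elastin gene, by 2.27 ± 0.26 (adjusted p = 6.4e-07). BCAN, a matrix proteoglycan (ENSG00000132692, chromosome 1, 156611182 to 156629324), rose by 2.68 ± 0.32 but stayed low, at 1.94 ± 0.332 CPM (SD, n = 3) with GO-L.

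Of 30 measured extracellular matrix genes, 26 rose, 0 fell and 4 did not pass, and the counts were the same when p was adjusted over the list alone, as they are below where only 1 pair of counts is given. The list was higher as a whole (median 0.61; adjusted p = 1e-17), and missed the threshold with an estimated correlation (adjusted p = 0.062). TNC, a matrix glycoprotein, rose by 1.28 ± 0.15 and COL5A1 by 1.16 ± 0.13. Targets of TGF-beta and YAP, signals that drive matrix and adhesion genes, also rose, 16 up and 1 down of 21 (adjusted p = 6.3e-13, adjusted p = 0.036 with an estimated correlation). Among them LTBP2, which binds matrix fibres, gained 1.39 ± 0.12 and SMAD7, a feedback inhibitor of the pathway, 0.97 ± 0.08. Actin and adhesion genes went the same way, 15 up and 3 down of 27, or 16 and 3 adjusted over the list alone, with the integrin ITGB5 at 0.89 ± 0.07 (adjusted p = 5.3e-05, adjusted p = 0.5 with an estimated correlation). Immediate early genes, which respond within minutes to growth signals, had 14 of 25 members higher and 0 lower (adjusted p = 3.8e-05, adjusted p = 0.43 with an estimated correlation), among them SPRY4 at 1.04 ± 0.14 and JUN at 0.69 ± 0.12. JUNB rose by 1.72 ± 0.40 and was past the threshold except without replicate 2 (adjusted p = 0.088; range 7.1e-06 to 0.088 over its alternatives).

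Ribosomal protein genes fell, 20 of 31 lower and 1 higher, or 21 and 1 adjusted over the list alone (median -0.50; adjusted p = 8.5e-19, adjusted p = 0.16 with an estimated correlation). RPL11 changed by -0.92 ± 0.05, to 598 ± 2.90 CPM with GO-US (SD, n = 3). Nuclear genes of oxidative phosphorylation fell in 28 of 34 cases and rose in 1 (median -0.43; adjusted p = 7.4e-22, adjusted p = 0.06 with an estimated correlation). COX6C, a subunit of cytochrome c oxidase, changed by -1.01 ± 0.05 and UQCRB, of complex III, by -0.99 ± 0.06. Both lists hold mostly short genes, and the libraries differed in how level depended on gene length: the slope was -0.196 ± 0.049 log2 units per doubling of length (SD, n = 3) in the short-term control and -0.005 ± 0.013 with GO-S at 8 µg/mL.

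Cell-cycle genes were lower. In the mitosis list 23 of 28 members fell and 1 rose, or 24 and 1 adjusted over the list alone (adjusted p = 1.8e-07, adjusted p = 0.5 with an estimated correlation), and 24 of 35 DNA replication genes fell while 6 rose (adjusted p = 0.0075, adjusted p = 0.59 with an estimated correlation). MKI67, the proliferation marker (ENSG00000148773, chromosome 10, 129894923 to 129924649), dropped from 985 ± 117 CPM (SD, n = 3) to 180 ± 8.94 with GO-US and changed by -0.93 ± 0.20 with GO-S, while its change with GO-L, -0.48, did not pass (adjusted p = 0.069). Interferon-stimulated genes, the antiviral programme, fell in 17 of 29 cases and rose in 1, or 18 and 3 adjusted over the list alone (adjusted p = 0.0043, adjusted p = 0.22 with an estimated correlation), with IFIT1 at -0.85 ± 0.09. NRF2 targets, which answer oxidative stress, were split: 14 of 26 fell, among them TXN at -0.89 ± 0.07 and AKR1B10 at -1.12 ± 0.12, and 5 rose, among them the transporter ABCC3 at 1.22 ± 0.13 (adjusted p = 0.0079, adjusted p = 0.5 with an estimated correlation). The NRF2 and DNA replication lists missed the threshold once trends on GC content and length were removed.

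Epithelial and keratinocyte genes had 14 of 31 members higher and 4 lower, or 16 and 4 adjusted over the list alone (adjusted p = 0.0088, adjusted p = 0.59 with an estimated correlation). OVOL1, an epithelial transcription factor, rose by 1.08 ± 0.18 and the keratin KRT15 fell by 0.70 ± 0.09 on the log2 scale. Of 14 matrix proteases and inhibitors 6 rose and 1 fell (adjusted p = 0.044, adjusted p = 0.68 with an estimated correlation); removal of the GC trend ended this call (adjusted p = 0.13). Among markers of other cell types, fibroblast markers rose in 5 of 8 cases (adjusted p = 0.0052, adjusted p = 0.44 with an estimated correlation); this list shares 5 genes with the extracellular matrix list. POSTN, on both, stayed at 0.607 ± 0.0396 CPM (SD, n = 3) with GO-L. Secretory and goblet cell markers fell in 4 of 5 measured cases (median -0.74; adjusted p = 0.0012, adjusted p = 0.036 with an estimated correlation), with AGR2 at -1.18 ± 0.09 and SLPI at -0.74 ± 0.10. Ciliated, haematopoietic and endothelial markers did not pass (adjusted p = 0.85, 0.33 and 0.89). For haematopoietic markers the median, -0.25, and the mean, 0.03, differed in sign.

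In total 7849 genes passed for the mean of the 3 materials at 8 µg/mL, 3390 higher and 4459 lower, of which 404 and 151 changed at least 2-fold (555 in all, against 281 with the GC trend removed). Single materials gave 6967 genes with GO-US, 6500 with GO-S and 5836 with GO-L. Libraries of replicate numbers 1 and 2 set much of this: the mean gave 4473 without replicate 1 and 3947 without replicate 2, GO-US 4227 and 2394, GO-S 3128 and 2988, and GO-L 1719 and 2420.

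**Figure D2:**
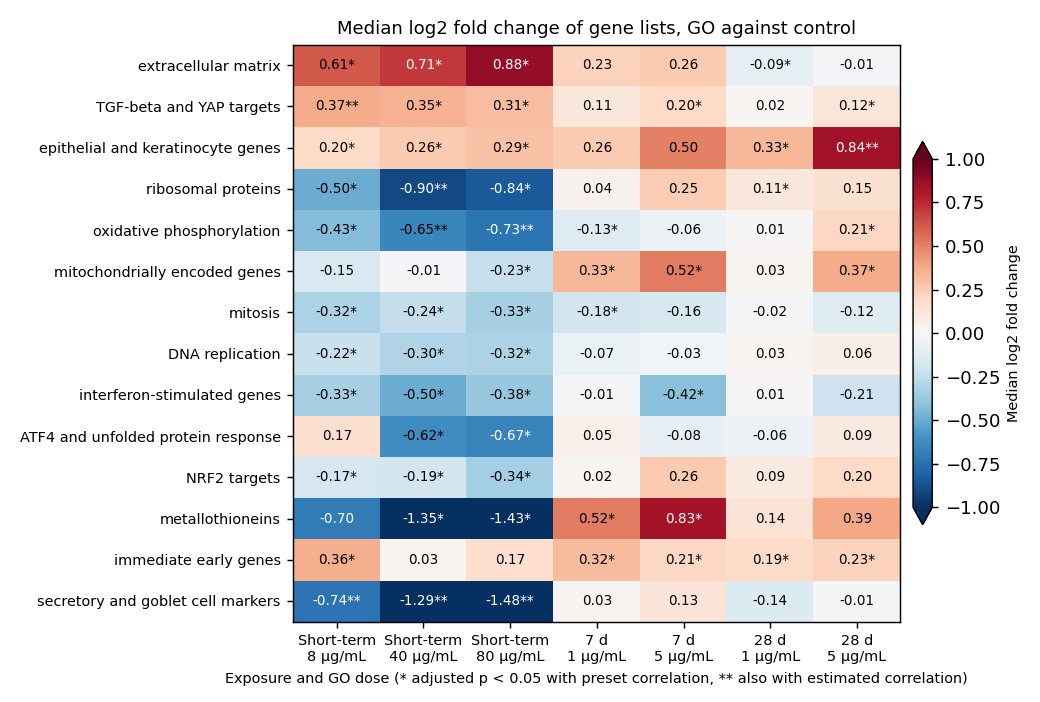
Median log2 change of the members of each gene list (colour and printed value) in the mean of the 3 materials against control, by list (vertical axis) and by time and dose (horizontal axis). A star marks adjusted p under 0.05 with the preset correlation, and a double star also with the estimated correlation. Ribosomal protein genes lie at -0.50, -0.90 and -0.84 in the short-term set, and epithelial and keratinocyte genes at 0.84 at 28 d and 5 µg/mL.

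At 40 µg/mL matrix genes were higher again, while genes of the amino acid stress response and metallothioneins fell. FBLN5, which assembles elastic fibres, rose by 2.40 ± 0.08 (adjusted p = 2.7e-17), from 66.9 ± 7.03 CPM (SD, n = 3) to 418 ± 14.3 with GO-L. BCAN gained 4.49 ± 0.30 and NOS1, the neuronal nitric oxide synthase, 3.05 ± 0.20. CSF3R, the receptor of granulocyte colony-stimulating factor, fell by 2.21 ± 0.11 on the log2 scale from 12.6 ± 1.47 CPM (SD, n = 3). ASNS, asparagine synthetase, changed by -2.24 ± 0.39 and INHBE by -2.75 ± 0.55, from control levels that varied widely (INHBE at 3.89 ± 2.77 CPM, SD, n = 3). In control replicate 2 ASNS stood at 70.9 CPM, inside the 33.8 to 81.3 CPM of the 40 µg/mL libraries, against 356 and 320 in the other controls.

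Extracellular matrix genes rose in 27 of 30 cases with 0 lower, or 28 adjusted over the list alone (median 0.71; adjusted p = 1.4e-19, adjusted p = 0.057 with an estimated correlation). FN1, fibronectin, rose by 0.68 ± 0.06, to 3429 ± 212 CPM with GO-L (SD, n = 3) and COL12A1 rose by 0.82 ± 0.06. TGF-beta and YAP targets had 15 of 21 members higher and 3 lower, or 16 and 3 adjusted over the list alone (adjusted p = 7e-09, adjusted p = 0.057 with an estimated correlation), among them INHBA at 1.24 ± 0.11 and SKIL at 0.95 ± 0.05. Epithelial genes rose in 18 of 31 cases and fell in 2, or 19 and 2 adjusted over the list alone (adjusted p = 0.0015, adjusted p = 0.5 with an estimated correlation); the desmosomal gene DSC3 rose by 0.71 ± 0.07 and KRT18 fell by 0.62 ± 0.06 on the log2 scale. Actin and adhesion genes (13 up, 2 down of 27, or 17 and 2 adjusted over the list alone; adjusted p = 0.0017, adjusted p = 0.6 with an estimated correlation) and matrix proteases (7 up, 3 down of 14; adjusted p = 0.031, adjusted p = 0.63 with an estimated correlation) were higher too. Fibroblast markers rose in 6 of 8 cases and fell in 1, or 7 and 1 adjusted over the list alone (adjusted p = 0.00011, adjusted p = 0.21 with an estimated correlation), with PDGFRB at 0.74 ± 0.07.

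All 6 measured metallothioneins, which bind zinc and copper, fell (median -1.35; adjusted p = 0.00025, adjusted p = 0.21 with an estimated correlation). MT1E dropped from 58.3 ± 7.51 CPM (SD, n = 3) to 12.5 ± 2.03 with GO-S. Of 25 genes of ATF4 and the unfolded protein response, 16 fell and 1 rose, or 18 and 1 adjusted over the list alone (adjusted p = 0.0065, adjusted p = 0.72 with an estimated correlation). ATF4 itself changed by -1.28 ± 0.17 and DDIT3, its proapoptotic target, by -1.83 ± 0.26. CHAC1, which degrades glutathione, changed by -1.93 ± 0.39, but missed the threshold without replicate 3 and with TPM values (adjusted p from 3.1e-05 to 0.057 over its alternatives). NRF2 targets had 14 of 26 members lower and 0 higher (adjusted p = 0.00015, adjusted p = 0.26 with an estimated correlation), with the ferritin light chain FTL at -1.23 with GO-S and NQO1 at -0.77 ± 0.07.

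Ribosomal protein genes fell in 30 of 31 cases with 0 higher (median -0.90; adjusted p = 2e-39, adjusted p = 0.036 with an estimated correlation), RPS12 by 1.22 ± 0.06 on the log2 scale. Genes of oxidative phosphorylation fell in 30 of 34 cases and rose in 1 (median -0.65; adjusted p = 4.7e-27, adjusted p = 0.039 with an estimated correlation), COX7C by 1.24 ± 0.06 on that scale. The slope on gene length at this dose was 0.024 with GO-US, 0.115 with GO-S and 0.017 with GO-L (mean, n = 3). DNA replication genes fell in 28 of 35 cases with 0 higher, or 29 adjusted over the list alone (adjusted p = 5.1e-08, adjusted p = 0.16 with an estimated correlation), PCNA, the replication clamp, by 0.64 ± 0.04 on the log2 scale. Mitosis genes fell in 18 of 28 cases, or 18 with 1 higher adjusted over the list alone (adjusted p = 0.0067, adjusted p = 0.74 with an estimated correlation), a call that ended with GC and length trends removed. Interferon-stimulated genes had 19 of 29 members lower and 1 higher, or 20 and 1 adjusted over the list alone, with OAS1 at -1.19 ± 0.15 (adjusted p = 0.0018, adjusted p = 0.21 with an estimated correlation). Secretory markers fell in 4 of 5 cases and rose in 1 (adjusted p = 0.00097, adjusted p = 0.036 with an estimated correlation), SLPI from 85.6 ± 24.4 CPM (SD, n = 3) to 28.4 ± 1.06 with GO-S. Ciliated, haematopoietic and endothelial markers again missed the threshold (adjusted p = 0.81, 0.75 and 0.63), with the haematopoietic median at -0.58, the mean at -0.24 and the test pointing up.

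The mean of the materials gave 8753 genes at 40 µg/mL, 3709 higher and 5044 lower. GO-US gave 6818, GO-S 8681 and GO-L 6445. Without replicate 1 these were 4543 for GO-US and 4232 for GO-L, and without replicate 2 GO-L gave 4130.

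At 80 µg/mL matrix genes and a mucin were higher. MUC16, the membrane mucin, rose by 2.37 ± 0.18 (adjusted p = 2e-10), from 4.32 ± 0.513 CPM (SD, n = 3) to 26.8 ± 7.92 with GO-US. MMP9, a gelatinase, gained 2.63 ± 0.51 but varied between libraries (3.53 ± 3.18 CPM with GO-S, SD, n = 3). COL1A1 rose by 2.54 ± 0.26, to 678 ± 68.4 CPM (n = 3) with GO-L, and TNC by 2.13 ± 0.16. Of 30 matrix genes, 29 rose and 0 fell (median 0.88; adjusted p = 5.3e-19, adjusted p = 0.06 with an estimated correlation). TGF-beta and YAP targets rose in 16 of 21 cases and fell in 1, with INHBA at 1.57 ± 0.11 (adjusted p = 2e-08, adjusted p = 0.06 with an estimated correlation). Among 31 epithelial genes 21 rose and 2 fell (adjusted p = 0.00061, adjusted p = 0.46 with an estimated correlation). The claudin CLDN4 rose by 1.97 ± 0.21 and OVOL1 by 2.01 ± 0.18, whereas KRT15 fell by 1.10 ± 0.09 on the log2 scale. Actin and adhesion genes were higher, 18 up and 1 down of 27 (adjusted p = 0.00015, adjusted p = 0.54 with an estimated correlation), as were fibroblast markers, 6 up and 1 down of 8 (adjusted p = 0.0017, adjusted p = 0.34 with an estimated correlation).

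Lower groups at 80 µg/mL were largely those of 40 µg/mL. Ribosomal protein genes fell in 28 of 31 cases with 0 higher (median -0.84; adjusted p = 1e-31, adjusted p = 0.055 with an estimated correlation), RPS27A from 867 ± 77.9 CPM (SD, n = 3) to 310 ± 31.6 with GO-S. Of 34 oxidative phosphorylation genes 29 fell and 1 rose, or 30 and 1 adjusted over the list alone (median -0.73; adjusted p = 1.3e-27, adjusted p = 0.036 with an estimated correlation), with NDUFA1, of complex I, at -1.45 ± 0.07. The length slope with GO-US was 0.056 ± 0.028 (SD, n = 3). NRF2 targets fell in 17 of 26 cases and rose in 1 (adjusted p = 9.1e-07, adjusted p = 0.15 with an estimated correlation), with TXN at -1.21 ± 0.06. Metallothioneins fell in 5 of 6 cases (adjusted p = 0.0024, adjusted p = 0.34 with an estimated correlation). Genes of ATF4 and the unfolded protein response fell in 16 of 25 cases and rose in 1 (adjusted p = 0.013, adjusted p = 0.75 with an estimated correlation), with DDIT3 at -1.95 ± 0.25.

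DNA replication genes fell in 26 of 35 cases and rose in 1 (adjusted p = 5.6e-07, adjusted p = 0.2 with an estimated correlation), with GINS2, of the replicative helicase, at -0.67 ± 0.05. Interferon-stimulated genes fell in 18 of 29 cases with 0 higher (adjusted p = 0.0041, adjusted p = 0.23 with an estimated correlation), and mitosis genes in 20 of 28 with 1 higher, or 22 and 1 adjusted over the list alone (adjusted p = 0.0025, adjusted p = 0.71 with an estimated correlation). DNA repair genes fell in 18 of 29 cases and rose in 3 (adjusted p = 0.043, adjusted p = 0.7 with an estimated correlation). Mitochondrially encoded genes fell in 8 of 13 cases and rose in 2, or 9 and 3 adjusted over the list alone, with MT-ND3 at -0.97 ± 0.07 (adjusted p = 0.026, adjusted p = 0.75 with an estimated correlation). Removal of the GC trend ended the calls of DNA repair (adjusted p = 0.12) and of mitochondrially encoded genes (adjusted p = 0.19), and removal of GC and length trends that of mitosis. Secretory markers fell in 4 of 5 cases and rose in 1 (median -1.48; adjusted p = 0.0014, adjusted p = 0.036 with an estimated correlation). Ciliated (adjusted p = 0.89), haematopoietic (0.52) and endothelial (0.81) markers missed the threshold; for ciliated markers the median, -0.08, and the test differed in direction, as did the haematopoietic median, -0.34, and mean, 0.01.

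At this dose 9796 genes passed for the mean, 4548 higher and 5248 lower, with 7796 for GO-US, 8929 for GO-S and 8606 for GO-L. Without replicate 2 the GO-L count was 5715.

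**Figure D3:**
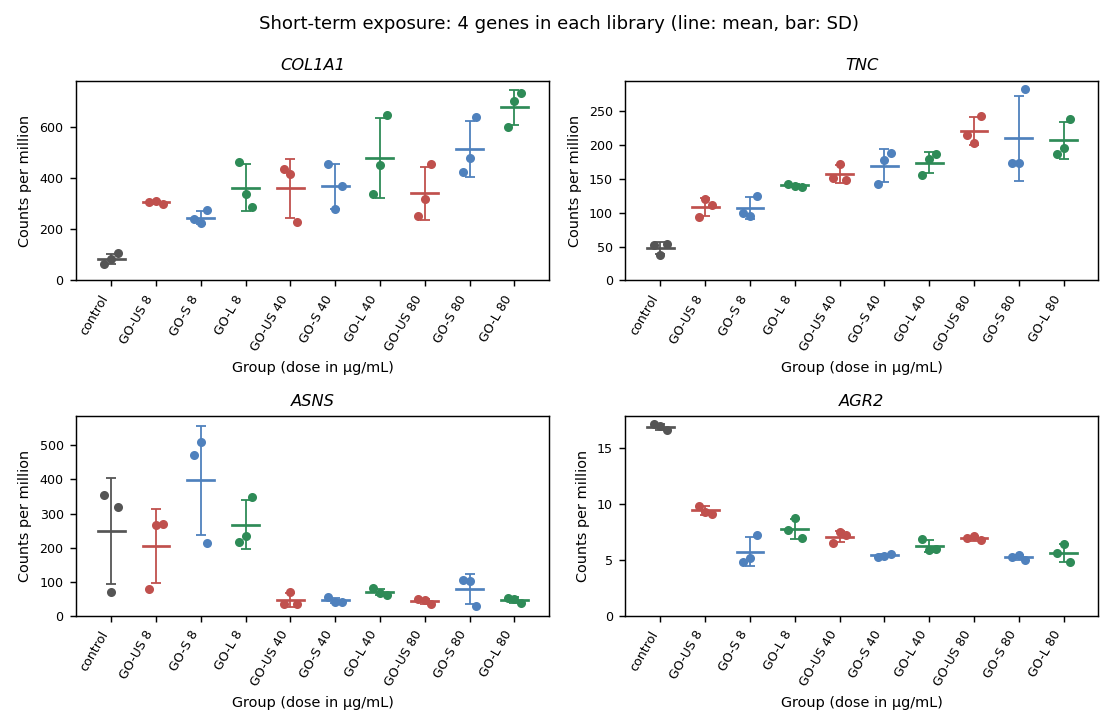
CPM (vertical axis) of COL1A1, TNC, ASNS and AGR2 in each short-term library (points), with the group mean (line) and SD (bar), by material and dose (horizontal axis). TNC lies at 48.4 CPM on average in the control and at 174 with GO-L at 40 µg/mL.

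Against 8 µg/mL, 80 µg/mL differed at 9052 genes in the mean of the materials, 4514 higher and 4538 lower. MUC16 was higher by 1.99 ± 0.11 and NOS1 by 1.61 ± 0.11. Lower at the high dose were INHBE at -3.54 ± 0.45, ADM2 at -2.65 ± 0.36, CHAC1 at -2.46 ± 0.31 and ASNS at -2.37 ± 0.32. The count was 5834 without replicate 1 and 5617 without replicate 2.

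The 3 short-term materials differed from each other most at the low dose, with 2932 genes at 8 µg/mL, 1095 at 40 and 579 at 80. IGF2, a fetal growth factor, stood at 9.19 ± 1.44 CPM with GO-US, 17.7 ± 0.999 with GO-S and 27.7 ± 1.31 with GO-L at 8 µg/mL, against 30.3 ± 3.69 in the control (SD, n = 3; adjusted p = 2.3e-09). RPS29, of the small ribosomal subunit, fell least with GO-US and most with GO-S (-0.56, -1.42 and -0.87 with GO-US, GO-S and GO-L; adjusted p = 1.8e-06), and ATP5E, of ATP synthase, had the same order (adjusted p = 2e-06), while the length slopes were -0.089, -0.005 and -0.063 (mean, n = 3). ZC3H13 changed most with GO-US, by -2.26, against -0.86 and -0.66 with GO-S and GO-L (adjusted p = 9.6e-06). At 80 µg/mL the aldo-keto reductase AKR1C2 stood at 15.3 ± 0.729 CPM with GO-US and 6.55 ± 1.21 with GO-S (SD, n = 3; adjusted p = 5.4e-06), and MT-CO2 at 4462 ± 277 and 2962 ± 120 (adjusted p = 0.00045). The counts at 8, 40 and 80 µg/mL moved with the replicate number left out. They were 3944, 898 and 639 without replicate 3, but 203, 18 and 24 without replicate 1 and 166, 10 and 0 without replicate 2, where edgeR still gave 1501 genes at an unadjusted p under 0.05 and no other tool was run. IGF2, RPS29, ATP5E and ZC3H13 at 8 µg/mL passed in 9 of 9 settings. AKR1C2 and MT-CO2 were among the genes lost without replicate 2 (adjusted p from 4.6e-20 to 0.1 and from 2.5e-11 to 0.12 over their alternatives). At 40 µg/mL chance is not excluded, since splits of the same libraries into other groups gave up to 2281 genes and 3 of 40, the real grouping among them, gave at least 1095.

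After 7 d at 1 µg/mL, most mitochondrially encoded and immediate early genes were higher and some cell-cycle and respiratory genes lower. MT-ND4, a mitochondrially encoded subunit of complex I, rose by 0.55 ± 0.07 (adjusted p = 0.00041), by 0.21 with GO-US, 0.41 with GO-S and 1.04 with GO-L, where it stood at 6403 ± 374 CPM (SD, n = 3). Mitochondrially encoded genes took 3.56 to 3.88% of the reads with GO-US, 4.31 to 4.55% with GO-S and 5.80 to 6.57% with GO-L, against 3.40 to 4.55% in the control. FOSB, a transcription factor of the immediate early class, rose by 0.94 ± 0.11 and EGR2 by 0.59 ± 0.08. JUNB (ENSG00000171223, chromosome 19, 12902310 to 12904124) rose by 1.57 ± 0.41 from a variable control level of 4.19 ± 3.09 CPM (SD, n = 3), and by 0.78 with the GC trend removed. COX7B, of cytochrome c oxidase, fell by 0.75 ± 0.08 on the log2 scale. These calls rest on few libraries, since without replicate 2 every gene named for this comparison missed the threshold (adjusted p = 0.18).

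Of 13 mitochondrially encoded genes 9 rose and 0 fell (median 0.33; adjusted p = 9.4e-06, adjusted p = 0.52 with an estimated correlation). Immediate early genes had 14 of 24 members higher and 1 lower (adjusted p = 5.6e-07, adjusted p = 0.21 with an estimated correlation). Mitosis genes fell in 17 of 28 cases and rose in 4, or 21 and 4 adjusted over the list alone (adjusted p = 0.0015, adjusted p = 0.59 with an estimated correlation). MKI67 was lower with GO-S and GO-L, at 183 ± 5.76 and 243 ± 11.2 CPM, and higher with GO-US, at 402 ± 5.81, against 320 ± 19.3 in the control (SD, n = 3). DNA repair genes fell in 18 of 29 cases and rose in 4, or 19 and 5 adjusted over the list alone (adjusted p = 0.01, adjusted p = 0.6 with an estimated correlation), with RAD51AP1, a recombination factor, at -0.51 ± 0.09. Oxidative phosphorylation genes fell in 18 of 34 cases and rose in 4, or 18 and 6 adjusted over the list alone (adjusted p = 0.0073, adjusted p = 0.2 with an estimated correlation), NDUFA4 by 0.58 ± 0.06 on the log2 scale. Of 10000 random lists matched on GC content, length and expression, 4172 had a median as low as the -0.13 of oxidative phosphorylation genes, and 1716 one as low as the -0.18 of mitosis genes. The length slope of GO-US libraries at this dose was 0.142, against 0 in the control (mean, n = 3).

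Actin and adhesion genes rose in 13 of 27 cases and fell in 4 (adjusted p = 0.016, adjusted p = 0.68 with an estimated correlation), and 2 of 6 metallothioneins rose (adjusted p = 0.042, adjusted p = 0.63 with an estimated correlation), with MT2A at 1.04 ± 0.29. Removal of the GC trend ended the calls of metallothioneins (adjusted p = 0.13), DNA repair (adjusted p = 0.23) and actin genes (adjusted p = 0.43), and removal of GC and length trends that of mitosis. Markers of ciliated (adjusted p = 0.44), secretory (0.89), fibroblast (0.086), haematopoietic (0.54) and endothelial (0.89) cells missed the threshold, with the secretory median, 0.03, and its test opposite in direction.

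The mean of the materials gave 7381 genes at 7 d and 1 µg/mL, 3569 higher and 3812 lower, GO-US 7215, GO-S 7371 and GO-L 36. Leaving out libraries moved these counts severely. The mean gave 54 genes higher and 74 lower without replicate 1 and 0 without replicate 2, where edgeR gave 4675 at an unadjusted p under 0.05 and no other tool was run. Without replicate 1, 2 and 3 GO-US gave 2907, 921 and 8442, GO-S 4316, 1 and 7013, and GO-L 24, 3 and 9. Without control replicate 1 alone, whose slope on GC content was -0.799 log2 units per 10 percentage points against -0.321 and -0.12 in the other controls, the mean gave 205, GO-US 4396 and GO-S 3903. GO-L gave 19 genes without control replicate 2 and 745 without control replicate 3. Removal of the GC trend gave 3215 genes for the mean, 1909 of them also called before it with the same sign and 273 with the opposite sign, and 203 for GO-L.

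**Figure D4:**
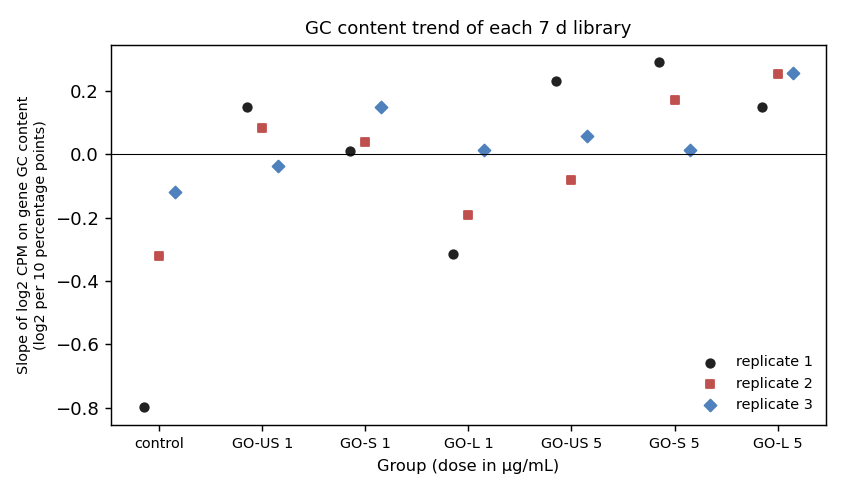
Slope of each 7 d library's log2 CPM, taken against the mean of all 7 d libraries, on gene GC content (vertical axis, log2 units per 10 percentage points of GC), by group (horizontal axis) and replicate number (symbol). The 7 d control libraries lie at -0.799, -0.321 and -0.12.

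At 5 µg/mL for 7 d, most mesenchymal and mitochondrially encoded genes measured were higher and most interferon-stimulated genes lower, in list calls lost with an estimated correlation. LSP1, an actin-binding protein of leukocytes (ENSG00000130592, chromosome 11, 1874200 to 1913497), rose by 2.92 ± 0.38 (adjusted p = 1.6e-05), or by 1.99 with the GC trend removed, from 0.442 ± 0.307 CPM (SD, n = 3) to 5.81 ± 0.328 with GO-L. TAGLN, a smooth-muscle actin-binding protein, rose by 1.79 ± 0.19. OAS2, an antiviral enzyme (ENSG00000111335, chromosome 12, 113416200 to 113449528), fell by 0.89 ± 0.10 on the log2 scale from 10.9 ± 1.41 CPM (SD, n = 3) to 3.64 ± 0.169 with GO-L. CRYBG3 (ENSG00000233280, chromosome 3, 97540884 to 97594132) fell by 1.82 ± 0.25 and SLC16A7, a monocarboxylate transporter, by 1.45 ± 0.16.

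Mesenchymal genes rose in 10 of 16 cases and fell in 4 (adjusted p = 0.044, adjusted p = 0.19 with an estimated correlation). ACTA2 changed by 0.57 ± 0.06 and VIM, from 700 ± 26.6 to 1167 ± 32.4 CPM with GO-US (SD, n = 3), by 0.43 ± 0.04. Mitochondrially encoded genes rose in 11 of 13 cases with 0 lower (median 0.52; adjusted p = 8.1e-07, adjusted p = 0.46 with an estimated correlation), MT-ND4 by 0.79 ± 0.07 (1.12, 0.68 and 0.56 with GO-US, GO-S and GO-L). Interferon-stimulated genes fell in 17 of 28 cases and rose in 3, or in 5 adjusted over the list alone (adjusted p = 0.00081, adjusted p = 0.16 with an estimated correlation). IFIT1 changed by -0.87 ± 0.10. Metallothioneins rose in 5 of 6 cases (adjusted p = 0.039, adjusted p = 0.63 with an estimated correlation), with MT1X at 0.97 ± 0.17. TGF-beta and YAP targets rose in 11 of 21 cases and fell in 4, or 12 and 4 adjusted over the list alone (adjusted p = 0.03, adjusted p = 0.45 with an estimated correlation), TGFBI by 0.49 ± 0.05, but 3155 of 10000 matched random lists had a median as high as their 0.20. DNA repair genes fell in 18 of 29 cases and rose in 5 (adjusted p = 0.0085, adjusted p = 0.6 with an estimated correlation), with LIG4, of end joining, at -0.91 ± 0.11.

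Immediate early genes had 14 of 24 members higher and 3 lower (adjusted p = 0.009, adjusted p = 0.59 with an estimated correlation); EGR1 rose by 0.48 ± 0.05, and by 0.10 with the GC trend removed, which ended its call (adjusted p = 0.14). With that trend removed the lists of metallothioneins (adjusted p = 0.099), DNA repair (adjusted p = 0.24), TGF-beta and YAP targets (adjusted p = 0.14) and immediate early genes (adjusted p = 0.7) missed the threshold as well, and JUNB and RTN4R shrank from 2.12 to 1.05 and from 2.32 to 1.04. Fibroblast markers rose in 4 of 6 cases (adjusted p = 0.023, adjusted p = 0.37 with an estimated correlation), COL1A2 from 2.75 ± 0.523 to 7.08 ± 0.956 CPM with GO-L (SD, n = 3). Ciliated (adjusted p = 0.26), secretory (0.89), haematopoietic (0.27) and endothelial (0.76) markers missed the threshold.

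For the mean 10520 genes passed, 5306 higher and 5214 lower, with 8618 for GO-US, 9222 for GO-S and 9906 for GO-L. Without replicate 1, 2 and 3 GO-S gave 1416, 0 and 9662 genes, with 7031 at an unadjusted p under 0.05 in edgeR for the count of 0 and no other tool run. GO-US gave 5672 without replicate 1 and 5522 without replicate 2, and GO-L 4085 without replicate 2. Without the GC trend GO-S gave 5677 and the mean 7737, of which 4789 were also called with it in the same direction and 1224 in the opposite one, and calls of at least 2-fold went from 1411 to 326.

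Between the doses at 7 d, 5293 genes differed, 2200 higher and 3093 lower at 5 µg/mL. The chemokine receptor CXCR4 was higher by 1.07 ± 0.07 and CA9, a carbonic anhydrase induced by hypoxia, by 0.90 ± 0.14. Interferon-stimulated OAS2, MX2 and IFI27 were lower, at -0.96 ± 0.07, -0.94 ± 0.12 and -0.91 ± 0.12. Without replicate 2 the count was 34 and CA9 and IFI27 missed the threshold (adjusted p from 4.4e-08 to 0.07 and from 6e-12 to 0.07 over their alternatives).

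Materials differed from each other at 4812 genes at 1 µg/mL and 4736 at 5 µg/mL after 7 d. GO-US stood apart in the genes with the smallest p. CKS2, a partner of cyclin-dependent kinases, was at 70.2 ± 2.24 CPM with GO-US at 1 µg/mL, against 130 ± 4.10 in the control (SD, n = 3), and changed by -0.89 with GO-US, 0.03 with GO-S and 0.10 with GO-L (adjusted p = 4.4e-09 among the materials). RPL27, of the large ribosomal subunit, was at 550 ± 18.7 CPM with GO-US and 936 ± 27.4 with GO-S, and SYNE2, which links the nucleus to actin, changed by 0.65 and -0.40. The length slope at this dose was 0.142 with GO-US, -0.087 with GO-S and -0.014 with GO-L (mean, n = 3), and CKS2 is a short and SYNE2 a long gene. With RPL27, both passed in 9 of 9 settings, removal of GC and length trends among them. At 5 µg/mL GO-US was again lowest for CKS2, at 62.4 ± 1.08 against 119 ± 10.3 with GO-S and 110 ± 1.21 with GO-L, and for FAM96A (adjusted p = 2.6e-08 for each). Without replicate 2 these counts fell to 936 and 1010, and without replicate 3 the 5 µg/mL count was 2391, while removal of the GC trend gave 7854 and 8484.

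After 28 d at 1 µg/mL few genes differed from control. PHACTR3, a regulator of phosphatase and actin (ENSG00000087495, chromosome 20, 58152564 to 58422766), rose by 1.32 ± 0.09 (adjusted p = 6.5e-07), from 7.88 ± 1.51 CPM (SD, n = 3) to 20.5 ± 1.29 with GO-US, 21.1 ± 0.780 with GO-S and 17.6 ± 0.320 with GO-L. BMF, a proapoptotic BH3-only protein, rose by 0.73 ± 0.05 from 83.1 ± 5.12 CPM (SD, n = 3), and the protocadherin PCDH19 by 1.38 ± 0.15. ABCA8, a lipid transporter, fell by 0.57 ± 0.05 on the log2 scale and DCLK1, a microtubule-associated kinase, by 0.89 ± 0.10. SLC7A11, the cystine transporter, was at 19.9 ± 1.26 CPM with GO-L against 49.0 ± 13.6 in the control (SD, n = 3) and missed the threshold whichever replicate number was left out (adjusted p from 0.00032 to 0.59 over its alternatives).

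Immediate early genes had 3 of 25 members higher and 0 lower, or 10 higher adjusted over the list alone (median 0.19; adjusted p = 2.5e-06, adjusted p = 0.22 with an estimated correlation), with DUSP4, a phosphatase of MAP kinases, at 0.43 ± 0.04. Extracellular matrix genes fell in 5 of 27 cases and rose in 1, or 10 and 2 adjusted over the list alone (adjusted p = 0.022, 0.58 with an estimated correlation). COL12A1 changed by -0.34 ± 0.06 and FN1 by -0.28 ± 0.05. Epithelial genes rose in 3 of 31 cases and fell in 1, or 9 and 3 adjusted over the list alone (adjusted p = 0.0033, 0.46 with an estimated correlation). Their median, 0.33, was 0.07 with the GC trend removed. KRT18 rose by 0.48 ± 0.07. Hypoxia and glycolysis genes had 2 of 29 members higher, or 13 higher and 2 lower adjusted over the list alone (adjusted p = 0.0025, 0.34 with an estimated correlation), with NDRG1 at 0.32 ± 0.05. The retinoid and glucocorticoid list (3 of 20 higher, adjusted p = 0.008, 0.23 with an estimated correlation) was led by TGM2, a transglutaminase, at 0.68 ± 0.08.

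Other lists with a call at this dose were cholesterol synthesis (1 of 25 higher, or 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.0052, adjusted p = 0.06 with an estimated correlation), ribosomal proteins (31 measured, median 0.11; adjusted p = 0.0084, adjusted p = 0.7 with an estimated correlation), aryl hydrocarbon receptor targets (1 of 7 higher, NQO1, or 2 adjusted over the list alone; adjusted p = 0.03, adjusted p = 0.2 with an estimated correlation) and actin genes (3 of 27 higher, 2 lower, or 7 and 3 adjusted over the list alone; adjusted p = 0.014, adjusted p = 0.54 with an estimated correlation). The actin call ended with the GC trend removed (adjusted p = 0.55). Ciliated (adjusted p = 0.28), secretory (0.32), fibroblast (0.8), haematopoietic (0.5) and endothelial (0.84) markers did not pass.

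The mean of the materials gave 317 genes, 140 higher and 177 lower, GO-US 69, GO-S 50 higher and 75 lower, and GO-L 791. Of the genes named here only PHACTR3 and BMF passed without replicate 2, where the counts were 2, 3, 3 and 6. Without replicate 3 they were 5, 5, 4 and 6, and without replicate 1 the mean gave 651, GO-S 5 and GO-L 1226. Materials differed at 60 genes (2 without replicate 1, 3 without replicate 3 and 0 without replicate 2, where 770 had an unadjusted p under 0.05 in edgeR and no other tool was run).

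Cells given 5 µg/mL for 28 d had more keratin RNA of the basal and stratified kind. KRT14, a basal keratin (ENSG00000186847, chromosome 17, 39738531 to 39743173), rose by 2.80 ± 0.24 (adjusted p = 1.5e-06), from 4.14 ± 1.51 CPM (SD, n = 3) to 19.5 ± 4.86 with GO-S (n = 3), 23.0 ± 0.400 with GO-L (n = 2) and 55.8 in the single GO-US library. KRT5, its partner (ENSG00000186081, chromosome 12, 52908359 to 52914471), rose by 1.78 ± 0.12 from 213 ± 44.2 CPM (n = 3) to 601 ± 63.2 with GO-S and 618 ± 38.8 with GO-L. The GO-US library had the highest GC slope at 28 d, 0.412. KRT6A, KRT16 and KRT17, keratins of activated keratinocytes, rose by 1.85 ± 0.14, 2.34 ± 0.21 and 1.91 ± 0.30, and KLK5, a protease of the epidermis, by 2.70 ± 0.26. Of 31 epithelial and keratinocyte genes 21 rose and 3 fell, or 22 and 3 adjusted over the list alone (median 0.84; adjusted p = 3e-14, adjusted p = 0.036 with an estimated correlation), the desmosomal PKP1 by 1.66 ± 0.10.

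PHACTR3 and PCDH19 rose by 2.05 ± 0.09 and 2.08 ± 0.15, and CCND2, cyclin D2, by 1.95 ± 0.11. DCLK1 fell by 1.86 ± 0.12, SLC16A7 by 2.03 ± 0.14 and ADAMTSL1 by 1.83 ± 0.11 on the log2 scale. ZBED6, which lies inside another gene, stood at 4.61 ± 0.576 CPM in the control, 1.22 ± 0.250 with GO-S and 0.728 ± 0.153 with GO-L (SD, n = 3, 3 and 2). CRYBG3 stood at 1.87 ± 0.295, 0.552 ± 0.104 and 0.348 ± 0.00904 CPM in the same groups, with 0 reads in the GO-US library.

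Cytokine genes under NF-kB rose in 6 of 23 cases and fell in 1 (adjusted p = 0.014, adjusted p = 0.12 with an estimated correlation), a call that ended with GC and length trends removed. The neutrophil chemokines CXCL1 and IL8 rose by 1.61 ± 0.10 and 0.60 ± 0.11 and the cytokine LIF by 0.77 ± 0.15. TGF-beta and YAP targets rose in 8 of 21 cases and fell in 2 (adjusted p = 0.0012, adjusted p = 0.21 with an estimated correlation), PMEPA1 by 1.02 ± 0.08, but 3475 of 10000 matched random lists had a median as high as their 0.12. Immediate early genes had 11 of 25 members higher and 2 lower, or 12 and 2 adjusted over the list alone (adjusted p = 0.00012, adjusted p = 0.34 with an estimated correlation), with DUSP4 at 0.74 ± 0.04. Hypoxia and glycolysis genes rose in 18 of 29 cases and fell in 3 (adjusted p = 0.00061, adjusted p = 0.24 with an estimated correlation); ENO1, enolase, rose by 0.51 ± 0.06 while HK2, hexokinase, fell by 0.38 ± 0.05 on the log2 scale. The retinoid and glucocorticoid list had 7 of 20 members higher and 4 lower, or 8 and 4 adjusted over the list alone (adjusted p = 0.016, adjusted p = 0.29 with an estimated correlation), with GLUL at 0.51 ± 0.05.

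Respiratory genes were higher at this time and dose: 19 of 34 oxidative phosphorylation genes rose and 4 fell, or 20 and 4 adjusted over the list alone (median 0.21; adjusted p = 0.0018, adjusted p = 0.59 with an estimated correlation), and 9 of 13 mitochondrially encoded genes rose and 1 fell (adjusted p = 0.00034, adjusted p = 0.6 with an estimated correlation). MT-CO2 went from 5716 ± 742 CPM (SD, n = 3) to 9178 ± 554 with GO-S (n = 3), and MT-ND4 changed by 0.01, 0.55 and 0.54 with GO-US, GO-S and GO-L. The length slope was -0.154 in the GO-US library and -0.076 with GO-L (mean, n = 2), against 0.033 in the control (mean, n = 3). Markers of ciliated (adjusted p = 0.28), secretory (0.7), fibroblast (0.73), haematopoietic (0.27) and endothelial (0.94) cells missed the threshold, with the secretory median, -0.01, and its test opposite in direction.

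**Figure D5:**
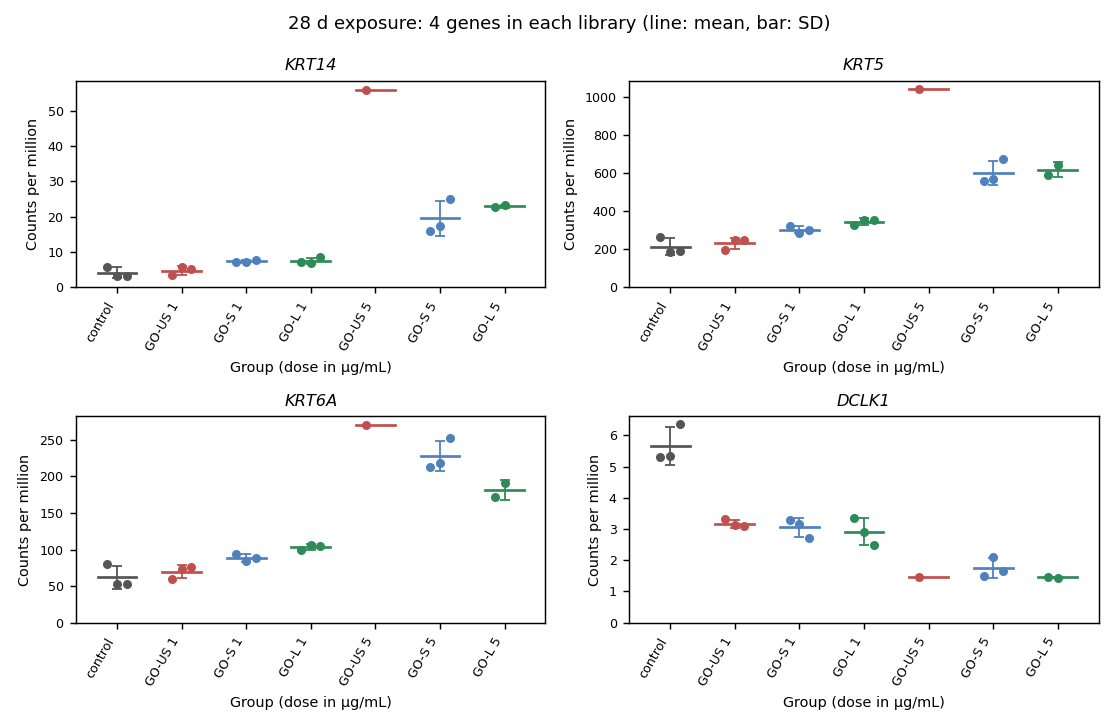
CPM (vertical axis) of KRT14, KRT5, KRT6A and DCLK1 in each 28 d library (points), with the group mean (line) and SD (bar), by material and dose (horizontal axis). KRT14 lies at 4.14 CPM on average in the control and at 55.8 in the single GO-US library at 5 µg/mL.

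For the mean 7595 genes passed at 28 d and 5 µg/mL, 3174 higher and 4421 lower, or 4223 with GO-S and GO-L only. GO-S gave 4168 (n = 3) and GO-L 3550 (n = 2). The fit gave 9182 for GO-US and 7737 between the materials. GO-US is a single library with a spread taken from other groups, so the 9182 measure no difference beyond that library, and it enters the 7737. Without replicate 1, which removes the GO-US library, the mean gave 3265. The mean gave 4883 without replicate 2, GO-S 1718 and 1832 without replicates 2 and 3, GO-L 2043 and 1835 without replicates 1 and 3 and 71 higher and 57 lower without replicate 2, and the difference between materials 2633 without replicate 2.

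Against 1 µg/mL, 5 µg/mL for 28 d differed at 6539 genes, 2294 higher and 4245 lower, or 3993 higher and 3790 lower with the GC trend removed. KLK5 was higher by 2.69 ± 0.18, KRT14 by 2.20 ± 0.15, CCND2 by 1.79 ± 0.08, KRT16 by 1.79 ± 0.14 and KRT15 by 1.63 ± 0.10, while KLHL11 was lower, at -1.62 ± 0.12. The count was 839 without replicate 1, 3606 without replicate 2 and 2576 with GO-S and GO-L only.

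Short against long exposure at an equal total dose was tested as the difference between the effects. This does not separate exposure length from other differences between the sets. At 8 µg/mL the short-term effect exceeded the 28 d effect on matrix genes and was lower on ribosomal and respiratory genes. TNC differed by 1.65 ± 0.18 and FN1 by 0.70 ± 0.08. Of 30 matrix genes 22 differed upward and 0 downward, or 28 and 0 adjusted over the list alone (median 0.71; adjusted p = 2.8e-26, adjusted p = 0.011 with an estimated correlation). TGF-beta and YAP targets differed upward in 13 of 21 cases with 0 downward, or 15 adjusted over the list alone (median 0.50; adjusted p = 1.7e-15, adjusted p = 0.0046 with an estimated correlation), CTGF by 0.83 ± 0.10. COL1A1 and KIAA1644 (ENSG00000138944, chromosome 22, 44639547 to 44708731) differed by 1.60 ± 0.32 and 2.05 ± 0.44, except without replicate 2 (adjusted p from 3.4e-08 to 0.088 and from 9.9e-06 to 0.18 over their alternatives).

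Oxidative phosphorylation genes differed downward in 27 of 34 cases with 0 upward (median -0.44; adjusted p = 2.1e-27, adjusted p = 0.036 with an estimated correlation), COX6C by -0.97 ± 0.08. Ribosomal protein genes did so in 22 of 31 cases (median -0.52; adjusted p = 6.4e-27, adjusted p = 0.055 with an estimated correlation) and mitosis genes in 16 of 28, or 21 adjusted over the list alone (adjusted p = 7.9e-08, adjusted p = 0.39 with an estimated correlation), with MKI67 at -1.15 ± 0.21. NRF2 targets differed downward in 10 of 26 cases and upward in 1, or 11 and 2 adjusted over the list alone (adjusted p = 4e-05, adjusted p = 0.15 with an estimated correlation), NQO1 by -0.69 ± 0.09. Cholesterol synthesis genes did in 7 of 25 cases, or 8 with 1 upward adjusted over the list alone (adjusted p = 0.0015, adjusted p = 0.59 with an estimated correlation), with FDPS at -0.69 ± 0.09, and chaperones in 7 of 15 (adjusted p = 0.0041, adjusted p = 0.46 with an estimated correlation). DNA replication genes did in 12 of 35, or 14 with 1 upward adjusted over the list alone (adjusted p = 0.00038, adjusted p = 0.34 with an estimated correlation). Interferon-stimulated genes did in 8 of 30, or 9 adjusted over the list alone (adjusted p = 0.0025, adjusted p = 0.16 with an estimated correlation). Metallothioneins did in 3 of 6, or 4 (adjusted p = 0.016, adjusted p = 0.52 with an estimated correlation). Mitochondrially encoded genes did in 3 of 13, or 4 (median -0.15; adjusted p = 0.042, adjusted p = 0.77 with an estimated correlation). Fibroblast markers were higher in 4 of 8 cases (adjusted p = 0.012, adjusted p = 0.38 with an estimated correlation). Actin genes were in 8 of 27, with 1 lower (adjusted p = 0.0043, adjusted p = 0.59 with an estimated correlation). Matrix proteases were in 4 of 14, with 1 lower adjusted over the list alone (adjusted p = 0.009, adjusted p = 0.5 with an estimated correlation). In the list of ATF4 and the unfolded protein response 1 of 25 was higher (adjusted p = 0.012, adjusted p = 0.74 with an estimated correlation). Immediate early genes were higher in 3 of 25 cases and lower in 1, or 4 and 1 (adjusted p = 0.03, adjusted p = 0.7 with an estimated correlation). Removal of the GC trend ended the calls of these 2 lists (adjusted p = 0.09 and 0.074) and of mitochondrially encoded genes (adjusted p = 0.18). Ciliated (adjusted p = 0.58), secretory (0.097), haematopoietic (0.94) and endothelial (0.91) markers missed the threshold. The count was 3528 genes, 1286 upward and 2242 downward, 2342 without replicate 1 and 1560 without replicate 2, and 5491 with the GC trend removed, of which 2819 were upward and 2672 downward.

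At 40 µg/mL in total, keratins separated the short-term from the 28 d effect. KRT14 differed by -2.62 ± 0.28, KRT15 by -2.37 ± 0.16 and KRT5 by -1.76 ± 0.13 (adjusted p = 1.6e-14), and 17 of 31 epithelial genes differed downward and 5 upward, or 17 and 6 adjusted over the list alone (adjusted p = 0.003, adjusted p = 0.5 with an estimated correlation). The cadherin CDH20 differed by 3.07 ± 0.34. Matrix genes were higher in 19 of 30 cases and lower in 2 (median 0.86; adjusted p = 1.1e-09, adjusted p = 0.13 with an estimated correlation), with COL12A1 at 1.35 ± 0.09. Oxidative phosphorylation genes differed downward in 31 of 34 cases with 0 upward (median -0.96; adjusted p = 1.2e-23, adjusted p = 0.036 with an estimated correlation), NDUFS3 by -1.15 ± 0.07. Ribosomal protein genes did so in 30 of 31 cases (median -1.13; adjusted p = 1.5e-24, adjusted p = 0.06 with an estimated correlation), RPL11 by -1.49 ± 0.09.

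Metallothioneins differed downward in all 6 measured cases (adjusted p = 0.0025, adjusted p = 0.35 with an estimated correlation), MT1X by -1.91 ± 0.18, and NRF2 targets in 17 of 26 with 2 upward, or 17 and 3 adjusted over the list alone (adjusted p = 3.8e-05, adjusted p = 0.15 with an estimated correlation), NQO1 by -1.33 ± 0.09. DNA replication genes differed downward in 25 of 35 cases and upward in 1 (adjusted p = 1.1e-06, adjusted p = 0.16 with an estimated correlation). Hypoxia and glycolysis genes did in 19 of 29, with 2 upward and TPI1 at -1.10 ± 0.08 (adjusted p = 0.0025, adjusted p = 0.42 with an estimated correlation), a call that ended with the GC trend removed (adjusted p = 0.12). Genes of ATF4 and the unfolded protein response differed downward in 17 of 25 cases and upward in 1 (adjusted p = 0.022, adjusted p = 0.76 with an estimated correlation). Cholesterol synthesis genes did in 14 of 25 with 4 upward (adjusted p = 0.027, adjusted p = 0.72 with an estimated correlation). Both calls also ended with the GC trend removed (adjusted p = 0.056 and 0.16). Mitochondrially encoded genes did in 8 of 13 cases with 2 upward, or 9 and 2 adjusted over the list alone (adjusted p = 0.0091, adjusted p = 0.71 with an estimated correlation). Mitosis genes did in 13 of 28 with 3 upward (adjusted p = 0.043, adjusted p = 0.78 with an estimated correlation). For mitosis 2148 of 10000 matched random lists had a median as low as the -0.24 measured. Of the markers of other cell types none passed: ciliated 0.66, secretory 0.071, fibroblast 0.058, haematopoietic 0.82 and endothelial 0.77 (adjusted p). The count was 9229 genes, 3718 upward and 5511 downward, and the median over all genes was -0.114.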

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

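Tests in this part of GC content and gene length, list medians against all genes, pseudogene reads and single control libraries were chosen after the results were seen. What the fit with GO-S and GO-L only and the splits would show was written down after them. Results in this paragraph and the next stand out because the effect of graphene oxide differed between short-term and 28 d cells at an equal total dose. At 8 µg/mL in total 3528 genes differed. Lists that passed with an estimated correlation were extracellular matrix (median 0.71), oxidative phosphorylation (-0.44, -0.22 in matched lists) and TGF-beta and YAP targets (0.50). KIAA1644 differed by 2.05, TNC by 1.65, SHROOM4 by 1.61 and COL1A1 by 1.60. Lower in the short-term effect were MBL1P at -2.08, C1orf95 at -1.94, HSD3BP4 at -1.49, CSF3R at -1.42 and ABCB5 at -1.27.

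At 40 µg/mL in total 9229 genes differed, with oxidative phosphorylation at a median of -0.96, against -0.57 in matched lists. ZBED6 differed by 3.88, part of which the single GO-US library may set, and CDH20 by 3.07. KRT14 differed by -2.62, KRT15 by -2.37, MAF by -2.28, MBL1P by -2.27 and DUSP23 by -2.27. With GO-S and GO-L only, CRYBG3, NOS1 and ZSCAN23 differed by 2.46, 4.07 and 1.54.

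The 7381 genes past the threshold at 7 d and 1 µg/mL are the first pattern weighed. Against GC content bias as the whole cause, 3215 genes passed with the GC trend of each library removed, but of these only 1909 were also called before with the same sign and 273 with the opposite sign, and calls of at least 2-fold fell from 401 to 54. A single control library setting the count has the value it needs: 205 genes passed without control replicate 1, against 4868 and 9130 without control replicates 2 and 3. That library may therefore set most of the count of the mean, though without it GO-US and GO-S alone still gave 4396 and 3903 genes, against 7215 and 7371, and the 3 control libraries were the shallowest of their 21, at 36.9, 39.8 and 38.8 M. The biological explanation in the design, exposure, stays open and untested apart from it.

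Lower ribosomal protein and oxidative phosphorylation genes in short-term cells are the second pattern. Against GC content and gene length as the whole cause, 0 of 10000 random lists matched on both had a median as low in any of 6 comparisons, with matched medians of -0.19, -0.32 and -0.32 for ribosomal proteins, against -0.50, -0.90 and -0.84. Scaling as the whole cause is argued against by the list medians relative to all genes, of which the nearest to 0 of 24 values was -0.39. Reads shared with pseudogenes stay open for ribosomal proteins. Most had few counted there, so adding those of 296 pseudogenes left the median nearest to 0 at -0.50. Lower expression of these genes after exposure stays a hypothesis, and part of the change may follow length, since the matched lists were lower too.

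Higher epithelial and keratinocyte genes at 28 d and 5 µg/mL are the third pattern. With GO-S and GO-L only, the list had 19 genes higher and 2 lower (median 0.77; adjusted p = 8.5e-21), which argues against the single GO-US library as the whole cause. Without GC and length trends its adjusted p was 1.8e-24, which argues against those. Both values and the reported 3e-14 use the preset correlation, and with it estimated the list passed narrowly. Whether more keratin RNA reflects a change in each cell or growth of some cells over others was not tested. A response to exposure remains a hypothesis.

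For the mean of the materials, only the real grouping among 40 splits gave as many genes, a share under 0.05. This argues against chance, but other splits mix materials, which can widen the spread. It neither singles out exposure nor excludes an odd library or a batch. Short-term 8 µg/mL gave 7849 against at most 484 in another split, 40 µg/mL 8753 against 4028 and 80 µg/mL 9796 against 9567. At 7 d, 1 µg/mL gave 7381 against 151 and 5 µg/mL 10520 against 4948. At 28 d they gave 317 against 0 and 7595 against 5266. The same held for 80 against 8 µg/mL (9052 against 5) and 5 against 1 µg/mL at 7 d (5293 against 1) and 28 d (6539 against 5295). Over 25 splits it held for the differences at 8 µg/mL (3528 against 1791) and 40 µg/mL in total (9229 against 4230). Among the materials it held for short-term 8 µg/mL (2932 against 2572) and 80 µg/mL (579 against 32), 7 d at 1 µg/mL (4812 against 3105) and 5 µg/mL (4736 against 3594) and 28 d at 1 µg/mL (60 against 7). At short-term 40 µg/mL it did not: 3 of 40 splits gave at least the real 1095, the highest other 2281.

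Comparisons of a single material with control allow 10 splits, too few for a share under 0.05. Real and highest other counts for GO-US, GO-S and GO-L were 6967 and 1, 6500 and 1053, and 5836 and 0 at short-term 8 µg/mL. At 40 µg/mL they were 6818 and 1, 8681 and 0, and 6445 and 0, and at 80 µg/mL 7796, 8929 and 8606 with 0 each. At 7 d and 5 µg/mL they were 8618 and 0, 9222 and 4843, and 9906 and 1, and at 28 d and 1 µg/mL 69 and 7, 50 higher plus 75 lower and 0, and 791 and 0, with 4168 and 0 for GO-S at 5 µg/mL. At 7 d and 1 µg/mL they were 7215 and 0, 7371 and 0, and for GO-L 36 and 3562, where 2 of 10 splits gave as many. What set the split with 3562 genes apart was not tested.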

How the results depend on the processing

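The alternatives with a GC or length trend removed, those without a single 7 d control library, the pairs of these and the one with GO-S and GO-L at both doses were chosen after seeing the data. Counts of genes lay within 1.5 times the reported count in 40 of 40 results with RLE size factors, 36 with no filter on low counts, 38 with the replicate number as a block, 33 with DESeq2, 26 with the GC trend removed, 28 with GC and length trends removed and 6 of 7 with TPM values. Of 106 list calls 12 passed with an estimated correlation, 89 with the GC trend removed and 85 with both trends removed. With GO-S and GO-L only, 19 of 20 list calls stayed, and that of ATF4 and the unfolded protein response in the difference at 40 µg/mL in total ended (adjusted p = 0.063). Of 304 results of named genes 303 stayed the same with RLE size factors, 301 with the GC trend removed and 240 without replicate 2. Depth was 36.9 to 72.4 M reads per library. Chi-square over degrees of freedom between libraries of a group had a median of 18.5 (lowest 2.22, counting error alone gives 1). What depth limits for genes near 1 CPM was not measured apart. In simulated counts, in which depth was not varied, a change of 0.5 on the log2 scale in the mean of 3 materials was found for 82.1% of 67 genes in the short-term set, 67.2% at 7 d and 83.6% at 28 d. With TPM values the median of all genes moved to 0.11, 0.21 and 0.23 at short-term 8, 40 and 80 µg/mL and to -0.16 at 28 d and 5 µg/mL. The share of called genes that were higher moved with it, from 43.2, 42.4 and 46.4% as reported to 76, 78.7 and 79.8% at 8, 40 and 80 µg/mL, and from 41.8 to 15.7% at 28 d and 5 µg/mL. At 28 d and 1 µg/mL it moved from 44.2 to 30.9% for the mean with RLE size factors, for GO-US from 68.1 to 55.9% with RLE size factors and 48.6% with DESeq2, and for GO-S from 40 to 29.9% with DESeq2, as it did from 69.4 to 58.3% for GO-L at 7 d and 1 µg/mL with DESeq2. With the GC trend removed the share moved from 42.4 to 51.4% at short-term 40 µg/mL, from 46.4 to 52.1% at 80 µg/mL, and from 41.8 to 50% at 28 d and 5 µg/mL. It moved from 35.1 to 51.3% for 5 against 1 µg/mL at 28 d, and from 36.5 to 51.3% and from 40.3 to 48.7% for the differences at 8 and 40 µg/mL in total. For the difference at 40 µg/mL in total the median of all genes was -0.114 as reported and -0.01 with RLE size factors.

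With no filter on low counts, 7 d at 1 µg/mL gave 4061 genes and 28 d at 1 µg/mL gave 541, GO-S 191, and the difference among materials 1.5e+02 (rounded, against 60 reported, with 47 genes in common). The replicate block gave 43 for GO-US and 26 for the difference among materials at 28 d and 1 µg/mL. DESeq2 gave 1711 for the difference among materials at 80 µg/mL, 72 for GO-L at 7 d and 1 µg/mL and, at 28 d and 1 µg/mL, 716 for the mean, 1.4e+02 for GO-US (rounded, 70 higher and 74 lower), 281 for GO-S, 1684 for GO-L and 225 for their difference. TPM values gave 24 for the mean at 28 d and 1 µg/mL. With GO-S and GO-L only, 28 d at 5 µg/mL gave 4223 and 5 against 1 µg/mL 2576, where fewer libraries enter. In the others the cause was not tested.

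Removal of the GC trend gave 4653, 2569 and 1335 for the difference among materials at short-term 8, 40 and 80 µg/mL, 7854 and 8484 at 7 d and 1 and 5 µg/mL, and 665 at 28 d and 1 µg/mL. It gave 3215 for the mean and 203 for GO-L at 7 d and 1 µg/mL, 5677 for GO-S at 7 d and 5 µg/mL, 873, 378 and 640 for the mean, GO-US and GO-S at 28 d and 1 µg/mL, 5430 for GO-L at 28 d and 5 µg/mL and 5491 for the difference at 8 µg/mL in total. With GC and length trends removed the difference among materials gave 4737 and 1207 at 8 and 80 µg/mL, 8417 at 7 d and 5 µg/mL and 734 at 28 d and 1 µg/mL. The mean, GO-US and GO-L at 7 d and 1 µg/mL gave 3244, 4005 and 211, GO-S at 7 d and 5 µg/mL 5658, and the mean, GO-US, GO-S and GO-L at 28 d and 1 µg/mL 985, 492, 714 and 1326. With the GC trend removed and control replicate 1, 2 or 3 left out, the mean at 7 d and 1 µg/mL gave 704, 1829 and 4526. The cause of these shifts was not tested beyond the trend removed.

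EIF3C at 7 d and 1 µg/mL reversed with TPM values, from -0.75 to 0.14. The list of mitochondrially encoded genes, lower in the difference at 8 µg/mL in total (adjusted p = 0.042), reversed with GC and length trends removed (list mitochondrially encoded genes, adjusted p = 0.018). In both the cause was not tested.

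Leaving out a replicate number, or at 7 d a control library, moved counts as follows. Short-term 8 µg/mL ranged from 3947 to 8425 for the mean, 2394 to 7054 for GO-US, 2988 to 7659 for GO-S, 1719 to 7117 for GO-L and 166 to 3944 for their difference. At 40 µg/mL GO-US ranged from 4543 to 6274, GO-L from 4130 to 5199 and the difference from 10 to 898. At 80 µg/mL GO-L ranged from 5715 to 8048 and the difference from 0 (edgeR; 1501 at an unadjusted p under 0.05) to 639, and 80 against 8 µg/mL from 5617 to 9298. At 7 d and 1 µg/mL the mean ranged from 0 (edgeR; 4675 at an unadjusted p under 0.05) to 9130, GO-US from 921 to 8712, GO-S from 1 to 8974, GO-L from 3 to 745 and the difference from 936 to 4150. At 7 d and 5 µg/mL the ranges were 5522 to 10122 for GO-US, 0 (edgeR; 7031 at an unadjusted p under 0.05) to 10083 for GO-S, 4085 to 10479 for GO-L and 1010 to 6478 for the difference, and 34 to 4783 for 5 against 1 µg/mL. At 28 d and 1 µg/mL they were 2 to 651 for the mean, 3 to 56 for GO-US, 3 to 5 for GO-S, 6 to 1226 for GO-L and 0 (edgeR; 770 at an unadjusted p under 0.05) to 3 for the difference. At 28 d and 5 µg/mL they were 3265 to 5079 for the mean, 1718 to 3192 for GO-S, 1.3e+02 (rounded, 71 higher and 57 lower) to 2043 for GO-L and 2633 to 8163 for the difference, 839 to 5627 for 5 against 1 µg/mL, and 1560 to 4310 for the difference at 8 µg/mL in total. Fewer libraries enter each of these fits; no other tool was run on them.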

Other observations

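The test in this part was chosen after its result was seen. Genes past the threshold at short-term 40 µg/mL and at 28 d and 5 µg/mL, a pair with an equal total dose, went in opposite directions more often than chance pairing of the calls gives. Of 17009 genes measured at both times, 1606 were higher short-term and lower at 28 d, where 880.5 are expected, and 1339 were lower and then higher, where 921.5 are expected. The same direction was rarer than expected, with 462 higher at both times against 632.5 and 951 lower at both against 1282.8. With GC and length trends removed the opposite calls numbered 1257 against 939.8 and 1347 against 893.1, which argues against these trends as the whole cause of the opposite calls. The deficit of same-direction calls nearly ended there, at 923 against 932.9 and 822 against 899.7. The other pair with an equal total dose, short-term 8 µg/mL and 28 d at 1 µg/mL, went the other way, with 62 higher at both times against 27.1 and 54 lower at both against 45, and opposite calls at 23 against 34.1 and 22 against 35.8. With the GC trend removed that pair gave 186 genes higher and then lower against 105.4 expected, 93 lower and then higher against 94.2, 97 lower at both times against 115.8 and more genes higher at both than the 85.7 expected. With both trends removed, that pair exceeded expectation in both, with 121 and 109 opposite calls against 96.1 and 94.7 and more calls in the same direction than the 86.8 and 104.9 expected. That acute and long exposure may move partly opposite gene sets is a hypothesis, found and tested on the same data, and the lower pair went both ways.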
